A study of Danio rerio with 15 samples.

How the data were processed

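RNA of zebrafish tailbuds was measured in 15 samples, 3 in each of 5 groups: untreated, 50 µM SU5402 and 0.3 M LiCl at 3 h, and untreated and SU5402 at 7 h. Groups and replicate numbers came from the labels. Per the labels' protocols, total RNA of dissected tailbuds was labelled with Cy3 from 50 ng by a low-input one-colour protocol and hybridised to Agilent arrays. Per the submitters' processing notes and the file headers, the authors extracted the spots with Agilent Feature Extraction 10.7.3.1, and the deposited scanner files hold linear intensity values per spot, including a processed signal with background subtracted and detrended within each array, and flags. The deposited series matrix holds log2 values whose normalization the sources used here do not give. Its columns have equal means (6.739) and ranked the probes as the processed signal did (0.993 on untreated 3 h replicate 1), so its scale and direction were settled from the data while its centring stayed unknown, and 0 columns were left unmapped.

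The main values were log2 of the processed signal minus the 75th percentile of each array. Control spots and spots with an outlier flag were left out, and spots of one probe were averaged. Accessions of the 43603 probes were named through the RefSeq table, in which 13609 of 28811 accessions had a symbol; the others keep their accession. Each gene name was represented by its probe with the highest mean signal over all arrays, and a feature was tested if it was well above background on every array of at least 1 group, which left 20998 features, 11497 of them with a symbol. Where a gene was not above background on any array of a group, the fold is a bound, the bright group's mean against the mean of, per array, the higher of the lowest signal well above background and the probe's own. Brightness per array limits how low a signal could be measured, and the number of arrays limits the precision.

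All 5 groups entered one linear model with a mean per group and 9 residual degrees of freedom (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided moderated tests). Comparisons were SU5402 against untreated at 3 h and at 7 h, LiCl against untreated at 3 h, untreated 7 h against 3 h, the difference of both SU5402 effects, and LiCl against SU5402. Adjusted p-values are Benjamini-Hochberg values over all tested features of a comparison, and a feature was called under 0.05. 23 gene lists fixed before the data were examined covered Fgf targets, Fgf ligands and receptors, Wnt targets, Wnt ligands, receptors and antagonists, tailbud and presomitic mesoderm, segmentation clock and Notch, somite formation, muscle, notochord and floor plate, neural, posterior Hox, retinoic acid, Bmp, Hedgehog, cell cycle, immediate early, heat shock and unfolded protein, p53, and osmolyte genes, and markers of epidermis, of blood and endothelium, of neural crest and pigment, and of yolk, endoderm, pronephros and ciliated cells. Of 458 list entries 409 were found on the array. Lists were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, adjusted over the 23 lists of a comparison.

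Named genes followed a rule fixed before the data were examined: in each comparison against untreated tailbuds or over time, the 5 called genes with a symbol and the largest rise and the 5 with the largest fall whose groups did not overlap, 17 fixed genes of the pathways whether called or not, and up to 4 called members of each list; for LiCl against SU5402, the 4 largest in each direction. Overlaps against the same untreated arrays were set beside 100 simulations of unchanged groups.

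The scripts were tested on simulated values with planted changes in 20998 features. For SU5402 at 3 h, 0% of planted changes of 0.5 on the log2 scale, 28.4% of those of 1 and 69.7% of those of 2 were recovered, with 2 false calls; for LiCl the shares for 1 and 2 were 28.4% and 86.4%, for SU5402 at 7 h 28.4% and 81.8%, over time 23.9% and 80.3%, for the difference of the SU5402 effects 7.5% and 68.2%, and for LiCl against SU5402 28.4% and 71.2%. Of 200 lists without a planted change, 8 had a camera p under 0.05. The simulated genes varied independently, whereas the estimated correlation of the posterior Hox list was 0.445. This share therefore does not show how camera behaves for lists of correlated genes. Each simulated feature also had the same spread on every array, whereas deviations from the group (root mean square) ranged from 0.258 to 0.59 on the real arrays. The recovered shares and false calls therefore do not show how the gene tests behave with unequal spreads, which were largest at 3 h with SU5402 and untreated.

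Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, median centring, the series matrix values, no background filter, a filter on all 15 arrays, other probes of a gene, all probes tested separately, the groups of a comparison alone, an intensity trend with robust estimation, slide as a fixed or random block, slide and scan as a random block, the replicate number as a block, each array left out in turn, a 2-fold minimum, an adjusted p under 0.01, and the set tests named above. Chosen after seeing the data were the removal of SU5402 3 h replicate 3 with untreated 3 h replicate 1, array brightness as a covariate, array weights, normexp with offset 0, and normexp without untreated 3 h replicate 1. Normexp was planned on mean spot signals and was run on median spot signals, since the scanner files used here had no column of mean signals.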

Results

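RNA levels were measured on one-colour Agilent arrays in tailbuds dissected from zebrafish embryos of the TLAB strain. Embryos had been freed of their chorions at the 4-somite stage and then kept in 50 µM SU5402, an inhibitor of Fgf receptor kinases, in 0.3 M LiCl, which inhibits Gsk3 and thereby raises canonical Wnt signalling, or in embryo medium alone. Tailbuds were collected after 3 h from all 3 conditions and after 7 h from untreated and SU5402-treated embryos, with 3 arrays in each of the 5 groups. The series asks how Fgf and Wnt signalling act on one another in the tailbud. The labels name no vehicle control for SU5402, and they do not say that replicates came from separate clutches or pools, so p-values measure only the spread between these samples.

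The arrays differed in brightness. The 75th percentile of the processed signal was 2571 on replicate 3 of SU5402 at 3 h and lay between 316.5 and 1713 on the other arrays, and 87.2% of probes were well above background on that array, against 66.6% to 80.2% elsewhere. Correlations between arrays of one group lay between 0.96 and 0.99, and no spot was saturated. The 3 untreated 3 h arrays shared slide 1 with replicate 1 of SU5402 at 3 h, and replicate 2 of that group shared slide 2 with LiCl replicates 1 and 2. LiCl replicate 3 lay on slide 3 with the 3 untreated 7 h arrays, the 3 SU5402 7 h arrays filled slide 4, and SU5402 3 h replicate 3 lay on slide 5. Values below are log2 fold changes ± SE from 3 arrays against 3, unless stated otherwise. For fgf8a every value that involves untreated tailbuds at 3 h rests on 2 untreated 3 h arrays. A gene is called changed where its adjusted p was under 0.05 over 20998 tested features. SEs and p-values rest on a spread shared by all 5 groups. Root mean square deviations from the group were 0.357 to 0.59 on untreated and SU5402 arrays at 3 h. On LiCl and 7 h arrays they were 0.258 to 0.357. The shared spread is thus likely too small for SU5402 against untreated at 3 h and too large at 7 h.

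**Figure D1:**
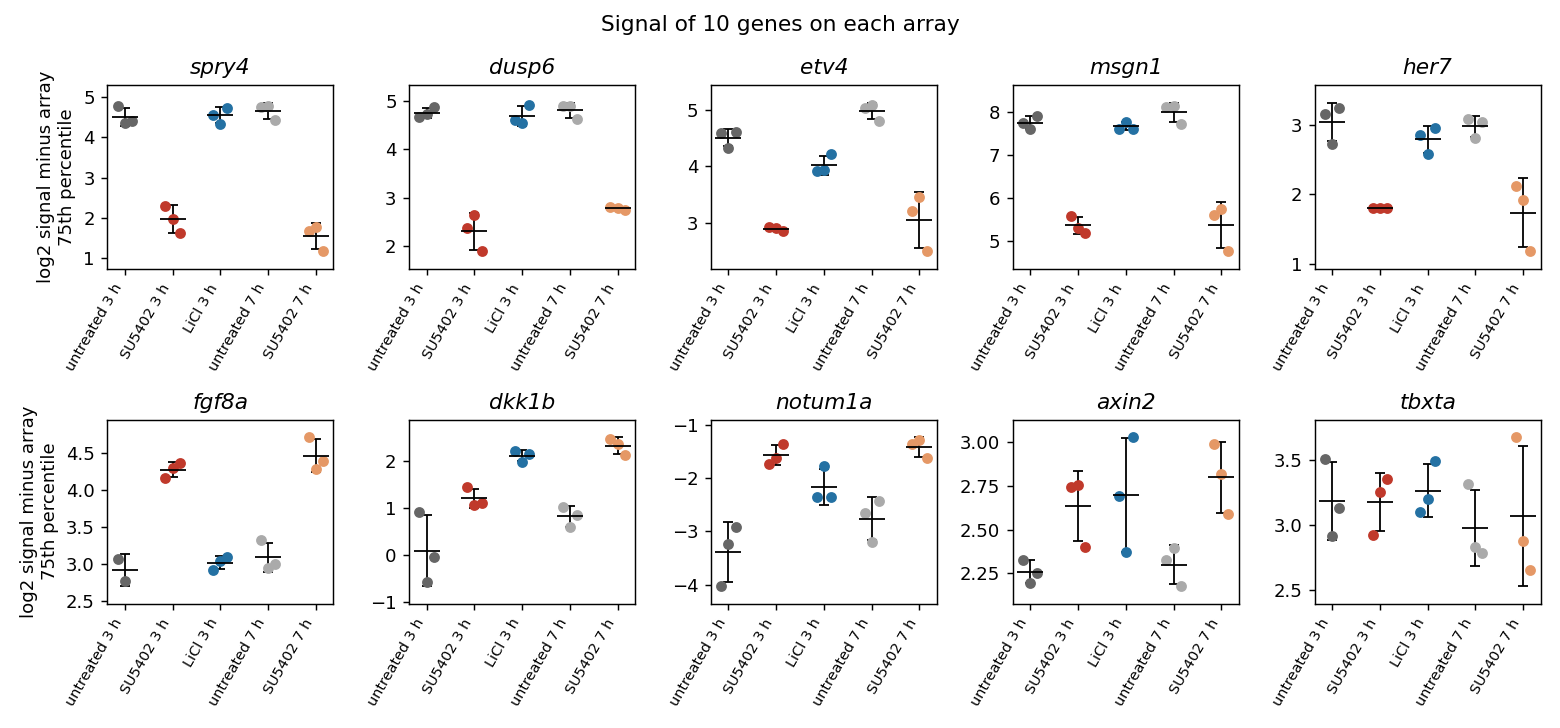
Normalised log2 signal (log2 of the processed signal minus the 75th percentile of the array, vertical axes) of 10 genes in the 5 groups (horizontal axes). Points are single arrays, dashes the mean and bars 1 SD; fgf8a has 2 untreated 3 h values because an outlier spot was left out. spry4, dusp6, etv4, msgn1 and her7 were lower on all 3 SU5402 arrays than on any untreated array at 3 h, whereas tbxta and axin2 were not called in any comparison against untreated tailbuds.

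SU5402 for 3 h lowered the feedback regulators and transcriptional targets of Fgf signalling. The Erk pathway inhibitors spry4 and dusp6 were 5.85-fold and 5.51-fold lower than in untreated tailbuds (-2.55 ± 0.22, adjusted p = 8.87e-05, and -2.46 ± 0.19, adjusted p = 3.47e-05). The ETS factors etv4 and etv5b fell by 1.61 ± 0.21 and 0.85 ± 0.16, and the immediate early gene ier2a fell by 2.99 ± 0.16 (adjusted p = 3.27e-06). Of 13 measured Fgf targets and feedback regulators, 8 fell, none rose and 5 were not called (11 lower when adjusted over the list alone), with a median of -1.05 (camera adjusted p = 5.77e-16, and 9.82e-05 with an estimated correlation). il17rd gave -0.99 ± 0.24 without passing the test (adjusted p = 0.0766). The ligand gene fgf8a rose by 1.35 ± 0.18 (2 untreated arrays), while the 13 other measured Fgf ligands and receptors were not called and that list did not shift (median -0.05, camera adjusted p = 0.9).

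Several genes of the presomitic mesoderm and several posterior Hox genes fell as well. msgn1, a bHLH factor of the presomitic mesoderm, fell by 2.40 ± 0.23, and tbx16l and tbx6 by 1.66 ± 0.19 and 1.03 ± 0.19, whereas tbxta (-0.01 ± 0.26) and tbx16 (-0.34 ± 0.23) were not called. Of 13 tailbud progenitor and presomitic mesoderm genes, 4 fell and 9 were not called (6 lower when adjusted over the list alone). Their camera adjusted p was 2.46e-05, and 0.153 with an estimated correlation. The segmentation clock genes her1, her7 and hes6 fell by 1.22 ± 0.25, 1.24 ± 0.22 and 1.32 ± 0.22, the other 15 members of that list were not called and the list as a whole did not pass (camera adjusted p = 0.0579). All 21 measured posterior Hox genes had negative fold changes, with a median of -1.24; 7 of them fell, including hoxc12a (-2.83 ± 0.52), hoxd13a (-2.41 ± 0.46) and hoxa11a (-1.95 ± 0.23), and 16 were lower when adjusted over the list alone. The camera adjusted p of the Hox list was 8.9e-16, and 0.153 with an estimated correlation.

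Wnt pathway genes moved in both directions. The largest fall among all called genes was that of wnt5a, a ligand of non-canonical Wnt signalling (-4.23 ± 0.38, above background on 1 of 3 SU5402 arrays). wif1 and sfrp1a, which encode secreted Wnt antagonists, fell by 1.90 ± 0.17 and 0.84 ± 0.16, while notum1a, encoding another secreted inhibitor, rose by 1.82 ± 0.29 and wnt8a rose by 0.74 ± 0.12. Among 11 Wnt targets and feedback regulators 1 rose, 1 fell and 9 were not called (3 higher and 4 lower when adjusted over the list alone), and the list did not shift (median 0.10, mean -0.02, camera adjusted p = 0.974). axin2 (0.38 ± 0.18), lef1 (-0.61 ± 0.19), dkk1b (1.11 ± 0.29) and sp5l (0.10 ± 0.16) were not called. Of 21 Wnt ligands, receptors and antagonists 1 rose and 2 fell (camera adjusted p = 0.316).

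Other genes that rose were sst6.1 (2.73 ± 0.29) and pdlim3b (1.99 ± 0.34), and nkx1.2lb, at least 3.93-fold higher, ndr1, at least 2.02-fold higher, and slc25a4, at least 2.79-fold higher, these 3 not well above background on the untreated arrays. With a normexp background correction the fold changes of nkx1.2lb, ndr1 and slc25a4 were -0.39, -0.97 and -0.70, where the median of all features was -0.48. six2a (-3.48 ± 0.60) and adamts15a (-3.23 ± 0.36) fell and were above background on 1 of 3 SU5402 arrays. In the retinoic acid pathway 2 genes rose and 2 fell out of 13; aldh1a2 and rdh10a, which encode enzymes of retinoic acid synthesis, rose by 1.31 ± 0.21 and 1.35 ± 0.28, and the list did not shift (camera adjusted p = 0.685). Among 27 neural genes sox3 (0.91 ± 0.17) and zic2b (0.81 ± 0.17) rose and elavl4 fell (-1.21 ± 0.24); the list was higher by camera (adjusted p = 0.0117, and 0.239 with an estimated correlation). Of 21 markers of yolk, endoderm, pronephros and ciliated cells none was called, 18 had positive values and the list was higher by camera (median 0.46, adjusted p = 0.00588, and 0.358 with an estimated correlation). The other lists, somite formation, muscle, notochord, Bmp, Hedgehog, cell cycle, immediate early, heat shock, p53, osmolyte, epidermis, blood and neural crest genes, were not called (camera adjusted p from 0.0772 to 0.974). Among them the immediate early list passed fry (median -0.33, fry adjusted p = 0.000434). Of the lists called by camera, the Fgf target, tailbud and Hox lists passed fry (fry adjusted p = 2.31e-08, 0.00109 and 0.00109). The neural list and the yolk, endoderm, pronephros and ciliated cell list did not (fry adjusted p = 0.0551 and 0.109).

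In all, 231 features were called at 3 h of SU5402, 66 higher and 165 lower, 176 of them by at least 2-fold. Within slide 1, with 1 SU5402 array against 3 untreated arrays, the Fgf target median was -1.22 and the Hox median -1.31. With normexp background correction 11 features were called, with slide as a fixed block, which rests on that 1 SU5402 array, 19 and with the 2 groups alone in the fit 12, against 231. Leaving out SU5402 replicate 2 or 3 gave 145 or 142 called features, and leaving out SU5402 replicate 3 and untreated replicate 1 together gave 125; the Fgf target median was negative in each alternative run.

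LiCl for 3 h raised a few Wnt feedback genes, while 12 of 13 Fgf targets and feedback regulators were not called. Small changes may have gone uncalled, since 0% of simulated changes of 0.5 were recovered for LiCl. dkk1b, a secreted Wnt antagonist induced by Wnt signalling, was 4.03-fold higher (2.01 ± 0.29, adjusted p = 0.00812), and notum1a and sp5a rose by 1.23 ± 0.29 and 0.74 ± 0.18. Of 11 Wnt targets and feedback regulators these 3 rose, none fell and 8 were not called (4 higher when adjusted over the list alone), among the latter axin2 (0.44 ± 0.18), lef1 (0.21 ± 0.19) and sp5l (0.16 ± 0.16). Their median was 0.32 (camera adjusted p = 0.00276, and 0.285 with an estimated correlation). With a normexp background correction notum1a was at -0.36, where the median of all features was -0.42. Of 13 Fgf targets and feedback regulators spred3 fell (-1.03 ± 0.25) and 12 were not called, including spry4 (0.03 ± 0.22), dusp6 (-0.06 ± 0.19), il17rd (-0.01 ± 0.24), etv4 (-0.48 ± 0.21) and etv5b (0.09 ± 0.16), and the list did not shift (median -0.06, camera adjusted p = 0.434). The tailbud and clock genes tbxta (0.08 ± 0.26), tbx16 (-0.15 ± 0.23), msgn1 (-0.09 ± 0.23), fgf8a (0.10 ± 0.18), wnt8a (0.05 ± 0.12), her1 (-0.04 ± 0.25) and her7 (-0.25 ± 0.22) were not called.

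Stress genes were among those that rose with LiCl. The stress-induced factor atf3 rose by 2.51 ± 0.43, and dnaja1, a co-chaperone gene, and atf4b rose by 1.30 ± 0.30 and 0.98 ± 0.19. Of 20 heat shock and unfolded protein response genes 2 rose and 18 were not called, with a median of 0.33 (camera adjusted p = 0.00487, and 0.383 with an estimated correlation). Of 14 p53 response genes tp53inp1 and bbc3 fell (-1.90 ± 0.34 and -0.98 ± 0.18) and none rose (camera adjusted p = 0.434). pdcb was at least 4.13-fold higher and scpp9 at least 1.2-fold higher, with no untreated array well above background for either and normexp values of -0.43 and -0.85, and serpinb1l4 (3.15 ± 0.34) and myhb (2.41 ± 0.27) rose. hoxc12a (-3.07 ± 0.52), cyp24a1 (-2.05 ± 0.28) and sparta (-2.04 ± 0.33) fell, and aldh3a1 was at least 1.37-fold lower; trpm1b was called lower without a measurable fold, being not well above background on any LiCl array.

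By camera, posterior Hox genes (1 of 21 called, median -0.38, adjusted p = 0.000361), neural genes (elavl4 lower, -1.06 ± 0.24, and 26 of 27 not called, adjusted p = 0.0204) and blood and endothelium markers (0 of 17 called, median -0.36, adjusted p = 0.0382) were lower with LiCl. With an estimated correlation the adjusted p of these lists was 0.536, 0.383 and 0.511. The Hox and blood lists did not pass fry (fry adjusted p = 0.111 and 0.0948), while the neural list did (fry adjusted p = 0.0324). Another probe of elavl4 gave 0.58. The osmolyte and ion transport list was included because 0.3 M LiCl also raises osmolarity. It had 0 of 16 genes called and did not pass camera (median 0.16, camera adjusted p = 0.238), but it passed fry (fry adjusted p = 0.0324). The remaining lists were not called by camera (adjusted p from 0.238 to 0.687), while immediate early genes passed fry (median 0.27, fry adjusted p = 0.0324).

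The LiCl comparison called 534 features, 231 higher and 303 lower, 226 of them by at least 2-fold; centring arrays on their median gave 234 higher and 185 lower. These calls depended on the spread shared by all 5 groups, since a limma fit of the 2 groups alone called 0 features (3778 had an unadjusted p under 0.05 with all groups). With all 5 groups kept in the fit, slide as a fixed block called 3 and normexp background correction 1. The cause of these 2 losses was not tested. Slide as a random block called 144, and leaving out LiCl replicate 1, 2 or 3 gave 51, 208 or 216, and untreated replicate 1 or 3 gave 169 or 216. Leaving out an untreated 7 h array, which enters only through the shared spread, gave 348, 343 or 295. LiCl and untreated arrays shared no slide, so no value within a slide was available.

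**Figure D2:**
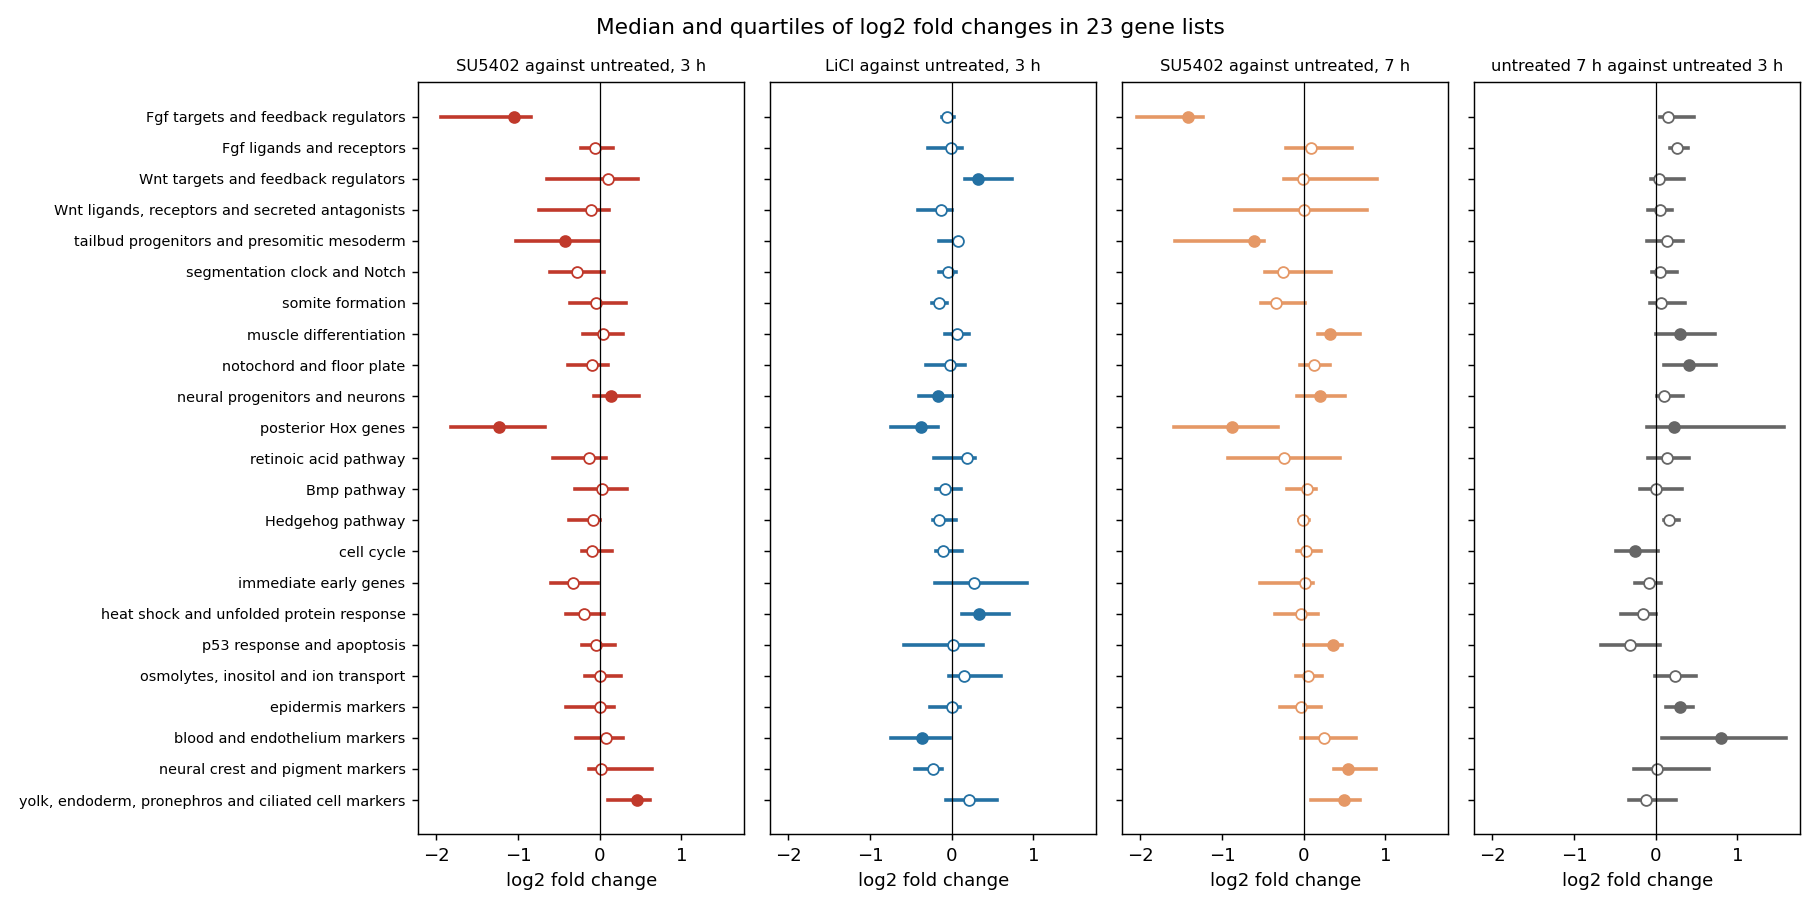
Median (circle) and quartiles (line) of the log2 fold changes (horizontal axes) of the measured members of 23 gene lists (vertical axis) in 4 comparisons. Filled circles mark lists called by camera with its preset correlation; the Fgf target medians were -1.05 with SU5402 at 3 h, -0.06 with LiCl and -1.42 with SU5402 at 7 h.

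After 7 h of SU5402 the Fgf targets were again lower than in untreated tailbuds of the same hour. spry4, dusp6, etv4, etv5b and il17rd fell by 3.13 ± 0.22, 2.04 ± 0.19, 1.92 ± 0.21, 1.42 ± 0.16 and 1.47 ± 0.24, and dusp4, another Erk phosphatase gene, was 11.1-fold lower (-3.48 ± 0.34, adjusted p = 0.000238). Of 13 Fgf targets and feedback regulators 10 fell, none rose and 3 were not called (10 lower when adjusted over the list alone), with a median of -1.42 (camera adjusted p = 3.57e-16, and 9.26e-05 with an estimated correlation). fgf8a and wnt8a rose by 1.37 ± 0.16 and 0.77 ± 0.12. msgn1 fell by 2.63 ± 0.23, and eve1, tbx16l and tbx6 fell by 2.92 ± 0.37, 1.68 ± 0.19 and 1.57 ± 0.19. Of 13 tailbud and presomitic mesoderm genes 5 fell and 8 were not called, among them tbxta (0.09 ± 0.26) and tbx16 (-0.49 ± 0.23), and the list was lower by camera (adjusted p = 5.34e-08, and 0.0704 with an estimated correlation).

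At 7 h 7 of 21 posterior Hox genes fell, among them hoxb13a (-2.93 ± 0.41) and hoxd13a (-2.13 ± 0.46), and the median was -0.88 (10 lower when adjusted over the list alone; camera adjusted p = 2.1e-10, and 0.237 with an estimated correlation). In the clock list her1 (-1.55 ± 0.25), her7 (-1.24 ± 0.22), hes6 (-1.55 ± 0.22) and her11 (-0.89 ± 0.19) fell, 1 of 18 rose and 13 were not called, and of 15 somite formation genes 1 rose and 2 fell, mespaa by 1.58 ± 0.34 (camera adjusted p = 0.395 and 0.277). Wnt targets again moved both ways, with dkk1b (2.83-fold, adjusted p = 0.0156), notum1a (1.34 ± 0.29) and sp5a (1.28 ± 0.18) higher, wif1 (-2.01 ± 0.17) lower and 7 of 11 not called, including axin2 (0.50 ± 0.18), lef1 (-0.06 ± 0.19) and sp5l (-0.01 ± 0.16). That list did not shift (median -0.01, mean 0.17, camera adjusted p = 0.49).

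The muscle and the neural crest and pigment lists were higher at 7 h of SU5402 by camera, while the epidermis, blood and notochord lists were not called (adjusted p = 0.996, 0.106 and 0.395). Of 23 muscle genes 3 rose, including ckma (1.49 ± 0.37) and actc1b (0.95 ± 0.23), and none fell (camera adjusted p = 0.00123, and 0.266 with an estimated correlation). Of 10 neural crest and pigment markers foxd3 (0.91 ± 0.19) and tyrp1b, at least 2.12-fold higher, rose (adjusted p = 0.000445, and 0.0704 with an estimated correlation); tyrp1b was at -0.18 with normexp, as was the median of all features. Neural genes (2 higher, among them sox3, 2.29-fold higher, and 1 lower of 27), p53 response genes (1 higher of 14) and markers of yolk, endoderm, pronephros and ciliated cells (2 higher and 1 lower of 21) were higher by camera (adjusted p = 0.0326, 0.0182 and 0.0326, and 0.36, 0.523 and 0.523 with an estimated correlation). The fatty acid receptor gene cd36 (3.89 ± 0.59), stra6 (3.43 ± 0.57), which encodes a retinol uptake receptor, sst6.1 (3.56 ± 0.29) and pdlim3b (3.06 ± 0.34) rose, and nkx1.2lb was at least 3.16-fold higher. wnt5a (-3.61 ± 0.38) and sst2 (-3.40 ± 0.51) fell, and the Notch pathway factor heyl was at least 8.48-fold lower and the Gdnf receptor gene gfra1b at least 3.49-fold lower. The remaining lists were not called (camera adjusted p from 0.106 to 0.996). Of the lists called by camera at 7 h, the p53 list and the yolk, endoderm, pronephros and ciliated cell list did not pass fry (fry adjusted p = 0.138 for both). The muscle, neural and neural crest lists did (fry adjusted p = 0.0253, 0.0253 and 0.00156), as did the Fgf target, tailbud and Hox lists.

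At 7 h 720 features were called, 336 higher and 384 lower, 463 of them by at least 2-fold; quantile normalization gave 400 higher and 307 lower. The SU5402 arrays filled slide 4 and the untreated arrays lay on slide 3, so slide and treatment cannot be told apart at 7 h. The 2 groups alone called 1552 features (459 higher and 1093 lower), slide as a random block 262, normexp background correction 74, and leaving out SU5402 replicate 2 or 3 or untreated replicate 1, 2 or 3 gave 366, 277, 325, 279 or 321. Leaving out SU5402 3 h replicate 3, which enters only through the shared spread, gave 1706.

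The SU5402 effects at both times were then set side by side. Of the 231 features called at 3 h, 42 were higher and 108 lower at 7 h as well, 1 went the opposite way, and chance overlap of independent lists would give 1.06 and 3.02. These comparisons share no array; across features, which are not independent replicates, the fold changes correlated with r = 0.438 (Spearman 0.425). Genes called at both times included spry4, dusp6, msgn1, wnt5a and hoxd13a among the lower ones and fgf8a, wnt8a, aldh1a2 and nkx1.2lb among the higher ones. Leaving out SU5402 3 h replicate 2, untreated 3 h replicate 3 or untreated 7 h replicate 2 gave 94, 98 or 99 shared features, and normexp background correction 11. The test of the difference between the 2 effects called 2 features, both without a symbol, and 1598 had an unadjusted p under 0.05, against 1050 by chance. It called 0 without untreated 3 h replicate 2, SU5402 3 h replicate 2, untreated 7 h replicate 1 or any SU5402 7 h array, and 0 with median centring, slide as a random block or a replicate block. Without SU5402 3 h replicate 3 it called 82, 9 higher and 73 lower. Its values for spry4 (-0.58 ± 0.31), dusp6 (0.42 ± 0.26), msgn1 (-0.23 ± 0.33), fgf8a (0.02 ± 0.24) and her7 (0.00 ± 0.32) were not called. By camera, muscle genes (median 0.30) and immediate early genes (median 0.34) differed between the times (adjusted p = 0.045 for both, and 0.458 and 0.278 with an estimated correlation). Fry called 0 of the 23 lists for this difference.

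**Figure D3:**
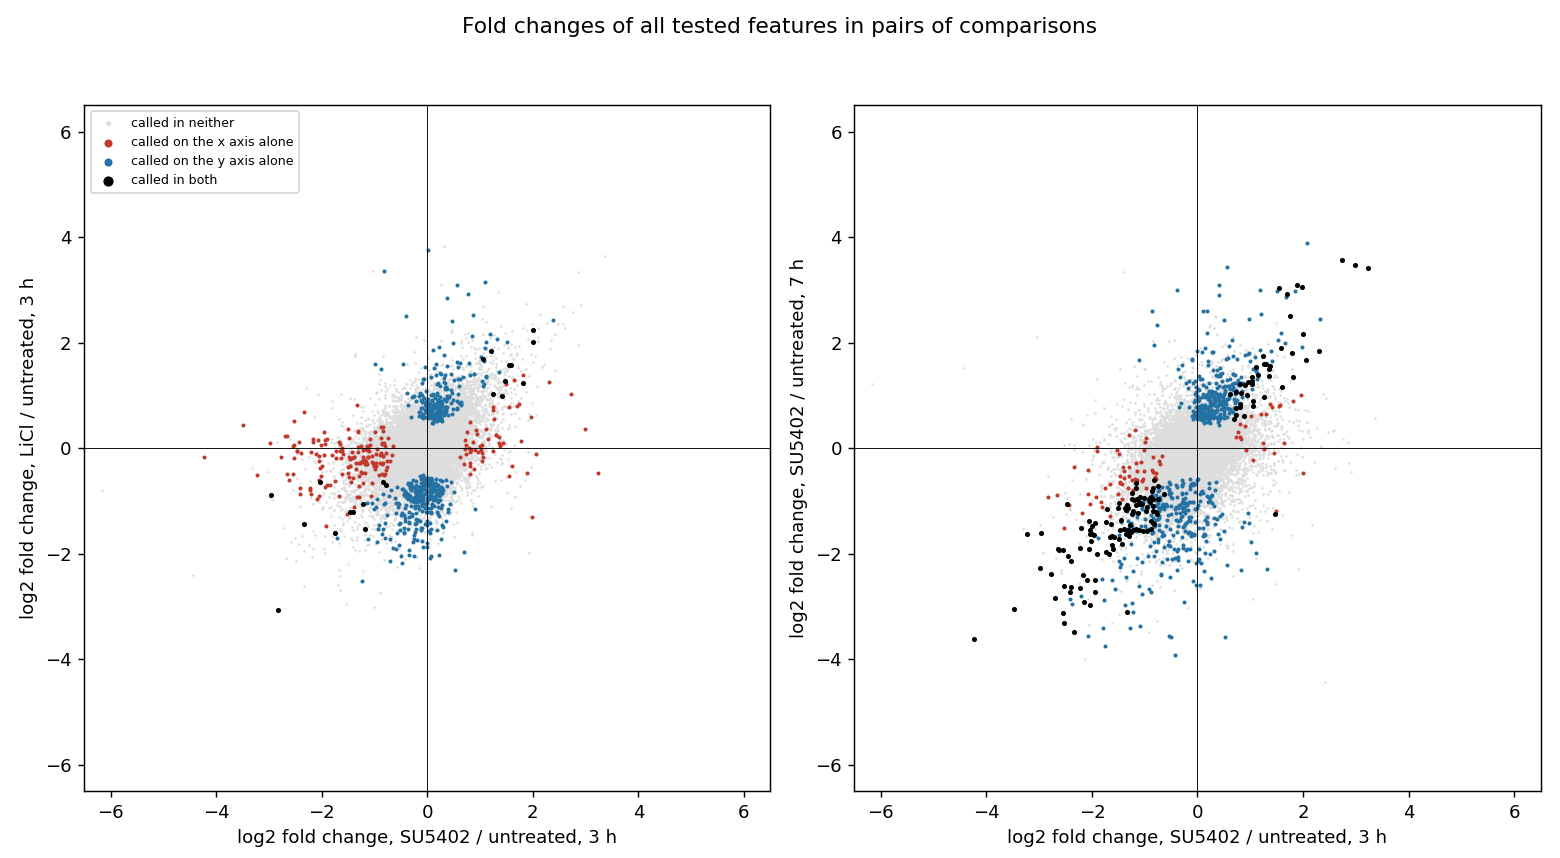
Log2 fold changes of all tested features, SU5402 at 3 h (horizontal axes) against LiCl at 3 h (left) and against SU5402 at 7 h (right). Colours mark calls; 21 features were called in both on the left, all with the same sign, and 150 were called with the same sign in both on the right.

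SU5402 and LiCl were compared to ask whether inhibiting Fgf receptors and activating Wnt signalling changed the same genes. 21 features were called in both at 3 h, 10 higher, among them notum1a, wnt16 and zic4, and 11 lower, among them hoxc12a and elavl4, with none in opposite directions. Independent lists would share 0.73 and 2.38. Simulated unchanged groups against the shared untreated arrays shared at most 1. Those simulations held no treatment effect, so hardly any feature could be called in both. Their count does not say how many of the 21 features the shared arrays made coincide. The fold changes correlated with r = 0.425 (Spearman 0.361), where the shared arrays alone gave 0.501, and their covariance was 0.116 against a simulated 0.0630. The simulation gave each feature the same spread on every array. Deviations from the group (root mean square) were 0.554, 0.42 and 0.357 on untreated 3 h arrays and 0.387 to 0.59 with SU5402 at 3 h. On LiCl and 7 h arrays they lay between 0.258 and 0.357. The simulated covariance may therefore be too low, and the excess decides nothing. In a check chosen after the result was seen, 1 untreated array served one comparison and the other 2 the other. Over the 6 ways to do this r lay between -0.071 and 0.155 (Spearman from -0.108 to 0.201) and the covariance between -0.0287 and 0.0501, so the correlation came at least in part from the shared arrays. Without SU5402 replicate 2 or 3, LiCl replicate 1 or 2, or untreated replicate 1, the number shared was 8, 12, 3, 8 or 9, and with normexp background correction it was 0. SU5402 replicate 2 lay on slide 2 with LiCl replicates 1 and 2, apart from the untreated arrays on slide 1. A shift of slide 2 could push both effects the same way, and fewer features were shared with slide as a random block.

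Set directly against each other, LiCl tailbuds had higher Fgf target levels than SU5402 tailbuds, with spry4, dusp6, etv4, etv5b and il17rd higher by 2.58 ± 0.22, 2.40 ± 0.19, 1.12 ± 0.21, 0.94 ± 0.16 and 0.98 ± 0.24. 9 of 13 members rose and none fell (median 0.98, camera adjusted p = 3.25e-09, and 0.0011 with an estimated correlation). msgn1 (2.31 ± 0.23), tbx16l (1.75 ± 0.19), her1 (1.18 ± 0.25) and her7 (0.99 ± 0.22) were higher with LiCl and fgf8a (-1.26 ± 0.16) and wnt8a (-0.69 ± 0.12) lower. Of 27 neural genes 4 were lower with LiCl, including zic2b (-1.09 ± 0.17) and sox3 (-0.94 ± 0.17), and the list was lower (camera adjusted p = 3.89e-06, and 0.0452 with an estimated correlation). Of 11 Wnt targets 3 were higher, lef1 by 0.82 ± 0.19 and cdx4 by 1.01 ± 0.20, as well as wif1 by 2.07 ± 0.17 (camera adjusted p = 0.00338, and 0.104 with an estimated correlation); dkk1b (0.90 ± 0.29), notum1a (-0.59 ± 0.29) and axin2 (0.06 ± 0.18) were not called. pdcb (4.18 ± 0.39), wnt5a (4.06 ± 0.38), six2a (3.93 ± 0.60) and egr4 (3.44 ± 0.68) were higher with LiCl and above background on 1 of 3 SU5402 arrays. pdlim3b (-3.29 ± 0.34) was lower with LiCl, as were nkx1.2lb, inhbab and gdf10a, by at least 4.16-fold, 1.62-fold and 1.61-fold.

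By camera, the Hox, tailbud, immediate early and heat shock lists were also higher with LiCl than with SU5402, and the blood and neural crest lists lower (camera adjusted p from 0.000101 to 0.0152, and from 0.0688 to 0.448 with an estimated correlation). This comparison called 1036 features, 445 higher and 591 lower. Within slide 2, with 2 LiCl arrays against 1 SU5402 array, the Fgf target median was 1.13 and the Wnt target median 0.03, and slide as a fixed block called 92 (58 higher and 34 lower). Leaving out LiCl replicate 1, 2 or 3 or SU5402 replicate 2 or 3 gave 350, 618, 486, 624 or 583, the 2 groups alone called 87 (58 higher and 29 lower), and normexp background correction called 11.

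Between 3 h and 7 h several blood and endothelium markers, several posterior Hox genes and a few muscle, notochord and epidermis genes rose in untreated tailbuds. The erythrocyte and endothelial genes slc4a1a (2.65 ± 0.39), hbae3 (1.82 ± 0.31) and cdh5 (1.65 ± 0.37) were among 8 of 17 blood and endothelium markers that rose, with none falling (median 0.80, camera adjusted p = 9.58e-05, and 0.132 with an estimated correlation). Of 21 posterior Hox genes 5 rose, led by hoxc13b (3.92 ± 0.77), hoxc13a (3.73 ± 0.70), hoxc12b (3.15 ± 0.68) and hoxb13a (2.11 ± 0.41), and 1 fell (camera adjusted p = 0.0302, and 0.666 with an estimated correlation). Of 23 muscle genes 3 rose, myog by 0.99 ± 0.18 and tnnt3a at least 2.56-fold, and of 16 notochord and floor plate genes loxl5b (0.84 ± 0.18) and col9a2 (0.68 ± 0.14) rose (camera adjusted p = 0.0141 and 0.00434, and 0.433 and 0.132 with an estimated correlation). The epidermis markers icn and icn2 rose by 1.24 ± 0.20 and 1.02 ± 0.21, and 17 of 19 were not called (adjusted p = 0.0184, and 0.448 with an estimated correlation). Of 20 cell cycle genes ccne1 (-0.71 ± 0.13) and rrm1 (-0.70 ± 0.14) fell (adjusted p = 0.00434, and 0.0846 with an estimated correlation).

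The sodium pump subunit genes atp1a1a.3 (5.61 ± 0.80) and atp1a1a.2, at least 6.26-fold higher, and heyl, at least 2.94-fold higher, rose, and fbxo6.2 (-2.44 ± 0.46), nme2a (-1.79 ± 0.35), the Bmp antagonist gene szl (-1.67 ± 0.43), ahsa1b (-1.65 ± 0.40) and the stress gene ddit3 (-1.57 ± 0.39) fell. atp1a1a.3 was above background on 1 of 3 arrays at 3 h, and fbxo6.2 and ahsa1b on 1 of 3 at 7 h. None of the 17 pathway genes fixed beforehand was called over time (limma; 4253 features had an unadjusted p under 0.05), with spry4 at 0.14 ± 0.22, dusp6 at 0.05 ± 0.19, axin2 at 0.04 ± 0.18, tbxta at -0.21 ± 0.26, fgf8a at 0.17 ± 0.18, wnt8a at 0.10 ± 0.12 and her7 at -0.06 ± 0.22, and the Fgf and Wnt target lists were not called (camera adjusted p = 0.332 and 0.642). The remaining lists were not called by camera (adjusted p from 0.0638 to 0.845). Among them Fgf ligands and receptors (median 0.25, fry adjusted p = 0.00961) and osmolyte and ion transport genes (median 0.23, fry adjusted p = 0.00678) passed fry. Of the lists called by camera over time, the Hox and epidermis lists did not pass fry (fry adjusted p = 0.182 and 0.0617). The blood, muscle, notochord and cell cycle lists did (fry adjusted p from 0.000562 to 0.0256).

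Over time 1047 features were called, 656 higher and 391 lower, 473 of them by at least 2-fold. No slide held both groups. With slide as a fixed block, estimated through slides shared with treated arrays, 1 feature was called, the Hox median turned from 0.22 to -0.40, the blood median dropped from 0.80 to 0.11, and szl and cdh5 changed sign (0.019 and -0.43). With normexp 17 features were called, the median of all features was -0.45 and tnnt3a (-0.93), slc4a1a (-0.65), cdh5 (-0.43), heyl (-0.75) and atp1a1a.2 (-0.031) were negative. Leaving out untreated 7 h replicate 1, 2 or 3 or untreated 3 h replicate 2 gave 293, 229, 273 or 572 called features.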

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

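The 2 features named here were singled out after their values were seen, and the count of splits by whether labels of a time stayed whole was chosen after the result was seen. The effect of SU5402 differed between 7 h and 3 h, by the test of the difference itself, for 2 features without a symbol. It called 0 features with median centring, normexp, no background filter, slide as a random block, a replicate block or the 12 arrays of these groups alone. The same held in 6 of the 12 runs with 1 of these arrays left out. Without untreated 7 h replicate 2 or 3 it called 1 or 2 features, but neither of these 2. Both were called without SU5402 3 h replicate 3 (82 called), with the series matrix (274 called) and with array weights (76 called). ENSDART00000058165 differed by 3.09 ± 0.39 (value 3.089, adjusted p = 0.0319), with -0.76 at 3 h and 2.33 at 7 h. NM_001002644 differed by 1.54 ± 0.19 (value 1.545, adjusted p = 0.0319), with 0.27 at 3 h and 1.81 at 7 h. The median difference of muscle genes was 0.2995 (0.046 at 3 h and 0.33 at 7 h, camera adjusted p = 0.045, and 0.458 with an estimated correlation). The median difference of immediate early genes was 0.3449 (-0.33 at 3 h and 0.014 at 7 h, camera adjusted p = 0.045, and 0.278 with an estimated correlation). Fry called 0 of the 23 lists for the difference.

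Of 100 splits of the 12 arrays of these groups, 8, the real one included, called at least 2 features as different between the SU5402 effects, and the highest of the other splits called 487. These splits do not decide whether chance gave the 2 features. In 16 of them, among which 6 called as many, the labels of a time were kept or exchanged as a whole, so that the whole SU5402 effect of that time stayed in the difference, as in the split with 487. Of the 83 splits that mixed the labels at both times 1 called as many, with 4 features, but mixing also leaves part of each effect in the difference and widens the groups' spread.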

How the results depend on the processing

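Leaving out both outlying arrays, array brightness, array weights and the 2 further normexp runs were chosen after the data were seen. The Fgf target median with SU5402 stayed negative in the alternatives run, from -1.346 to -0.963 at 3 h and from -1.524 to -1.363 at 7 h with 1 array left out. The Wnt target median with LiCl lay between 0.242 and 0.437 with 1 array left out and was 0.157 with array weights, 0.661 and 0.673 with normexp at offsets 50 and 0, and 0.324 as reported, and its camera adjusted p was 0.285 with an estimated correlation. The Fgf target median with LiCl lay between -0.13 and 0.023 with 1 array left out and was 0.189 with normexp, not called in either case, and the Wnt target median lay between -0.004 and 0.185 with SU5402 at 3 h and between -0.096 and 0.112 at 7 h with 1 array left out. With all probes it was -0.163 at 3 h and -0.196 at 7 h, and with array brightness as a covariate 0.321 at 7 h. Of 5279 recomputed values of called named genes 5237 kept their sign and 42 reversed, and of 1712 values of uncalled ones 1525 kept it. Kept signs were largely fixed in advance, since these genes were chosen as called and several runs leave the fold change as it was. Calls were kept in 28 of 225 values with normexp at offset 50 and 93 of 225 with the groups alone. With 1 array left out 896 of 1350 were kept, and with quantile normalization 208 of 225. Dim probes limit what can be measured, since 66.6% to 87.2% of probes were well above background per array. The labels do not say that replicate numbers pair arrays; the median correlation was -0.02 for equal and 0.01 for other numbers, 7 of 15 arrays had their best partner under their own number, and pairs of SU5402 and untreated at 7 h lay between 0.09 and 0.41.

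Counts are given for SU5402 at 3 h, LiCl, SU5402 at 7 h, time, the difference of the SU5402 effects and LiCl against SU5402, then for features shared by SU5402 and LiCl and by both SU5402 times. As reported they were 231, 534, 720, 1047, 2, 1036, 21 and 150. Normexp with offset 50 gave 11, 1, 74, 17, 0, 11, 0 and 11, and with offset 0 it gave 8, 1, 37, 0, 0, 10, 0 and 6. The normexp fit of untreated 3 h replicate 1 had a background SD of 1765 against at most 35.9 on other arrays, and without that array normexp gave 63, 18, 652, 191, 0, 398, 1 and 53, so that array accounts for part of the loss at most and the remaining cause was not tested. Under normexp with offset 50 the median of all features was -0.48, -0.42, -0.18, -0.45, 0.29 and 0.14 in the 6 comparisons. The series matrix gave 396, 1277, 2005, 2338, 274, 1730, 65 and 228. Quantile normalization gave 1 and median centring 0 for the difference, and an intensity trend with robust estimation gave 1. No background filter tested more features and gave 191 for LiCl, 527 for time, 0 for the difference, 606 for LiCl against SU5402 and 5 shared by SU5402 and LiCl.

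The groups of a comparison alone, with fewer arrays to estimate the spread, gave 12, 0, 1552, 139, 0, 87, 0 and 12. Fewer arrays do not account for the higher count of 1552 for SU5402 at 7 h, where arrays varied less around their groups than SU5402 arrays at 3 h. Slide as a random block gave 144 for LiCl, 262 for SU5402 at 7 h, 198 for time, 0 for the difference and 5 shared by SU5402 and LiCl. Slide as a fixed block gave 19, 3, 1 for time, 92 for LiCl against SU5402 and 0 shared, and could not be fitted for SU5402 at 7 h or the difference. Slide and scan as a random block gave 332 for LiCl, 641 for time and 9 shared. The replicate number as a block gave 234 for LiCl, 535 for SU5402 at 7 h, 0 for the difference and 9 shared by SU5402 and LiCl. Array brightness as a covariate gave 137 for SU5402 at 3 h, 413 at 7 h, 5 for the difference, 611 for LiCl against SU5402, and 13 and 94 shared. Array weights gave 1382 for LiCl, 3641 for SU5402 at 7 h, 2336 for time, 76 for the difference, 2151 for LiCl against SU5402, and 49 and 233 shared. Without SU5402 3 h replicate 3 and untreated 3 h replicate 1 together the counts were 125 for SU5402 at 3 h, 2239 at 7 h, 24 for the difference and 8 shared by SU5402 and LiCl. An adjusted p under 0.01, a stricter limit by construction, gave 73, 50, 212, 147, 0, 268, 1 and 53, and a minimum of 2-fold gave 226 for LiCl, 463 for SU5402 at 7 h, 473 for time and 496 for LiCl against SU5402. With 1 array of the compared groups left out the counts ranged from 142 to 280, 51 to 555, 277 to 489, 229 to 836, 0 to 82, 350 to 1089, 3 to 25 and 94 to 145. Arrays of other groups enter through the shared spread, and without SU5402 3 h replicate 3 the counts were 684 for LiCl, 1706 for SU5402 at 7 h and 1457 for time, and without untreated 3 h replicate 1 they were 918 for SU5402 at 7 h and 1417 for LiCl against SU5402. Apart from the constructions named, the cause was not tested.

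Fold changes that reversed with normexp and offset 50 were nkx1.2lb (-0.392), ndr1 (-0.968) and slc25a4 (-0.696) with SU5402 at 3 h, pdcb (-0.427), scpp9 (-0.847) and notum1a (-0.36) with LiCl, tyrp1b (-0.18) with SU5402 at 7 h, atp1a1a.2 (-0.031), heyl (-0.749), tnnt3a (-0.925), slc4a1a (-0.647), cdh5 (-0.429) and slc20a1a (-1.122) over time, and slc20a1a (0.066) for LiCl against SU5402. With offset 0 they were ndr1 (-0.464), slc25a4 (-0.095), scpp9 (-0.692), notum1a (-0.263), heyl (-0.132), tnnt3a (-0.627), slc4a1a (-0.161), cdh5 (-0.091) and slc20a1a (-1.05) in the same comparisons. Without untreated 3 h replicate 1 and with normexp they were ndr1 (-0.163), tyrp1b (-0.18), tnnt3a (-0.111) and slc20a1a (-0.313 over time and 0.066 for LiCl against SU5402). With slide as a fixed block szl (0.019), fgfrl1a (-0.088), hbae1.1 (-0.068) and cdh5 (-0.428) reversed over time. Other probes reversed musk (-0.09) and crabp2a (0.132) with SU5402 at 3 h, elavl4 (0.577) with LiCl, foxa1 (-0.483) and foxj1a (-0.756) with SU5402 at 7 h, and slc4a1a (0.303), musk (0.633), hhip (0.342) and foxj1a (0.091 and 0.041) for LiCl against SU5402. With another probe, 95 of 212 values of called genes kept their sign but lost the call, beside the 10 that reversed. The cause of these reversals and lost calls was not tested.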

Other observations

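The genes of the first 2 paragraphs were singled out after their values were seen, and the test on tissue, that on shared arrays and the correlations with single SU5402 arrays were chosen after the result was seen. With SU5402 the homeobox genes nkx1.2la, gbx1 and emx3 fell at both times, while six1b and twist1a rose. nkx1.2la fell by 2.53 ± 0.32 at 3 h and by 3.31 ± 0.32 at 7 h, while its paralog nkx1.2lb rose (with normexp nkx1.2lb was at -0.39 and 0.10). gbx1 fell by 2.77 ± 0.22 and 2.38 ± 0.22, and emx3 by 2.55 ± 0.34 and 1.93 ± 0.34. gbx2 fell by 2.07 ± 0.25 at 3 h and was at -0.88 ± 0.25 at 7 h without passing the test (adjusted p = 0.0829). six1b rose by 1.24 ± 0.18 and 1.74 ± 0.18, and twist1a, a mesenchyme factor, by 0.82 ± 0.14 and 1.04 ± 0.14. Of 7 measured zic genes 3 rose and none fell at 3 h, among them zic4 (1.55 ± 0.27) and zic6 (1.61 ± 0.24, but -0.27 with normexp). wnt16 rose with SU5402 at 3 h (1.59 ± 0.29), with LiCl (1.58 ± 0.29) and with SU5402 at 7 h (1.90 ± 0.29), and was at -0.23 and -0.20 with normexp in the 3 h comparisons.

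Of 51 features called lower with LiCl and higher over time, 7 are given here, so their opposite directions follow from the choice, and no test asked whether their pathways changed. The glycolysis genes eno1a, eno1b, aldocb and gpia fell by 1.52 ± 0.25, 1.43 ± 0.29, 1.54 ± 0.23 and 1.09 ± 0.22 with LiCl and rose by 1.39 ± 0.25, 1.26 ± 0.29, 0.92 ± 0.23 and 1.34 ± 0.22 over time. The collagen genes col1a1a, col1a1b and col1a2 fell by 1.54 ± 0.33, 1.42 ± 0.32 and 1.16 ± 0.27 with LiCl, calls that were lost with median centring (adjusted p from 0.0521 to 0.0659), and rose by 2.29 ± 0.33, 2.09 ± 0.32 and 1.12 ± 0.27 over time. All 7 kept their signs with quantile normalization, median centring, the series matrix and normexp.

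All 21 posterior Hox genes had negative fold changes with SU5402 at 3 h, 7 of them called, with a list call lost at an estimated correlation (adjusted p = 0.153). Less tailbud tissue in the dissected piece would lower tailbud genes together, but 2 of 6 such genes, fgf8a and wnt8a, were called higher and 1 lower, with a median of 0.046, although these genes may respond to SU5402 themselves. The list of 13 tailbud and presomitic mesoderm genes fixed beforehand went the other way. Its median was -0.42, with 11 negative values, 4 genes called lower and 0 higher, so less tailbud tissue stays open. The Hox median of -1.238 was -1.126 with array brightness as a covariate (6 of 21 called), -1.312 with slide as a fixed block (1 of 21 called) and -1.226 without both outlying arrays (5 of 21 called), with fry p of 0.000899, 0.00223 and 0.00295. These values argue against brightness and the outlying arrays as the whole cause, and slide stays open, since with slide fixed the value rests on 1 SU5402 array against 3 untreated arrays. A response of Hox genes to the loss of Fgf signalling stays a hypothesis, found and tested on the same data.

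LiCl changes ran against the changes between 3 h and 7 h in 92 of 112 features called in both, where shared untreated arrays would push both the same way (covariance 0.0264, below the lowest simulated 0.0579). The share opposite among these features was 82.1% with array brightness as a covariate and 81.2% with slide as a fixed block, but it was fixed by choosing features called in both, so brightness and slide stay open. A candidate explanation is that LiCl tailbuds were at an earlier stage than untreated ones of the same hour. The LiCl effect then would run against the difference of SU5402 7 h and 3 h arrays, which shares no array with it, and across features, which are not independent replicates, it did (r = -0.317, Spearman -0.326). SU5402 3 h replicate 2 shares a slide with LiCl arrays and by itself would push r below 0; with replicate 3, which shares none, r was -0.212 (Spearman -0.212), and a change of metabolism without a change of stage was not tested.

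Each 2-group comparison of 3 arrays has 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many called features in each comparison. The real count and the highest of the other splits were 231 and 1 for SU5402 at 3 h, 534 and 0 for LiCl, 720 and 0 for SU5402 at 7 h, 1047 and 0 over time, and 1036 and 15 for LiCl against SU5402. Every other split mixes arrays of both groups, which puts any difference between them into the spread. Low counts there were thus largely fixed in advance, and the splits do not decide on chance.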
